A study of Mus musculus with 6 samples.

How the data were processed

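Poly(A) RNA of microglia isolated from adult mouse brain was sequenced on an Illumina NovaSeq instrument as paired reads of 150 bases, per the labels' protocols. The samples were 3 of microglial Piezo1 knockout 5×FAD mice and 3 of floxed 5×FAD littermates, and each was placed in its group by its title. The titles call them biological repetitions, without saying how many mice each sample came from, so p-values measure the spread between these samples.

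GRCm38, cutadapt 1.11, HISAT2, RSEM 1.2.30, DESeq2 and R 3.6.1 are named in the submitters' processing notes, with no order. The deposited table gives a normalised read count (a signal value that is never negative) per gene and sample, made by the authors. Every deposited normalised read count was a whole multiple of the value of 1 read in its sample (100% of values whole, at a tolerance of 1e-06), as gene counts divided by size factors give, and the size factors ranged from 0.979 to 1.03. The deposited log2 fold change compares knockout with control and is the authors' value. The deposited p-value and adjusted p-value are the authors' own, and the test that gave them is not stated in the file headers. For intervals implied by the authors' fold change and p, that p was assumed to come from a two-sided Wald test. The adjusted p-values correspond to a Benjamini-Hochberg adjustment over 19107 genes, computed from p, rank and adjusted p. All 466 genes in the deposited table had an unadjusted p-value under 0.05 and an absolute log2 fold change over 1, so the table is a selection made by the authors on these samples, and genes outside it were not analysed here. By chance alone, 955 of 19107 genes would have an unadjusted p under 0.05. That number has no limit on the fold change, so it cannot be set against the 466. The last of the 14 genes past an adjusted p of 0.05 had an implied rank of 15, so 1 gene ranked there was not analysed here. The sum of the table is not a depth, the depth of the libraries is unknown, and no interval that needs it was computed. A fold for a gene with no reads in a whole group was given as a lower bound against a floor of 3 reads in each library of that group, which covers counting error only.

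The comparison of the 2 groups was fitted with limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(value + 1), with no rescaling, no low-value filter and Benjamini-Hochberg adjustment over the 466 genes, at a threshold of 0.05. Fold changes from this fit are differences of mean log2(value + 1). For low or uneven genes they can be smaller or larger than the authors' fold changes. For Hba-a1 the fit gave -4.53 against the authors' -4.94, and for Trank1 -2.55 against -1.73. Standard errors and intervals from this fit borrow variance across the 466 genes. The adjustment over preselected genes is lenient, so the authors' adjusted p over 19107 genes is given first. The test was chosen for normalised values, since the table held no raw counts. edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 were run on the recovered whole reads with the size factors recovered from the authors' values, as alternatives. All 3 tests were first run on simulated data for 466 genes in 3 against 3 samples. The simulated genes were independent, unselected and of random direction, with a spread estimated from these samples. The real genes were selected and mostly lower, so the simulated shares do not carry over to the real counts. At true folds of 2, 4, 8 and 16, limma called 0%, 4%, 20% and 42% of 50 changed genes each, edgeR 0%, 8%, 16% and 34%, and DESeq2 6%, 14%, 32% and 60%. Of 266 unchanged genes, limma and edgeR called 0 and DESeq2 2.

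A total of 32 gene lists of microglial states, pathways, dissociation and other cell types was fixed before the data were examined. Since the table holds selected genes only, no enrichment was tested. The direction of a list was compared with that of the other listed genes by a two-sided Fisher's exact test for the 3 lists with at least 5 listed members, adjusted by the Benjamini-Hochberg method. The collagen, homeobox and motile cilium groups were added after the table was seen. Gene identifiers were matched to GENCODE annotation of GRCm38. All 466 had the same chromosome there and 458 the same start, and coordinates are those of the authors' table. Whether counting used strand is not given in the sources used here, so overlapping genes cannot be told apart. Transcripts of Rps27rt and Rps27 were aligned with Biopython 1.88.

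The rule for named genes, fixed before the data were examined, was Piezo1 and Cx3cr1, the 10 genes with the largest rise and the 10 with the largest fall among protein-coding genes (without Gm and Rik names) past an adjusted p of 0.05 with a mean of at least 100 and non-overlapping groups, and up to 4 genes past the threshold per list. With limma's adjusted p this rule named 0 genes beyond Piezo1 and Cx3cr1. With the authors' adjusted p its part on the largest changes named 3, which are Rps27rt, Cx3cr1 and Dusp18, and its part on lists named Cx3cr1 and 1500015O10Rik. The other named genes were chosen by a wider rule written after their values were seen. It takes the 14 genes past the authors' adjusted p, the listed members of the fixed lists, and the 10 with the largest change in each direction among genes with a mean of at least 20 and non-overlapping groups. Some genes that this rule would name are not reported here.

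Alternatives fixed before the data were examined were a replicate block, a rescaling to the median ratio of the listed genes, DESeq2, pseudocounts of 0.5 and 10, filters at a mean of 10 and 100, no trend, other thresholds, adjustment over all annotated genes, and leaving out each sample in turn. Alternatives added afterwards were edgeR on the recovered reads, adjustment over 19107 genes, leaving out controls 2 and 3 together, thresholds of 0.01 and 0.1 on the authors' adjusted p, and the settings run on the list medians. Figures were drawn with matplotlib 3.10.9.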

Results

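Microglia, the resident macrophages of the brain, were isolated from adult brain of male 5×FAD mice, a transgenic line that models Alzheimer's disease, and their poly(A) RNA was sequenced. The knockout group held 3 samples from mice that carried the tamoxifen-inducible Cx3cr1CreER-EYFP allele together with floxed Piezo1, which encodes a mechanically gated cation channel. The control group held 3 samples from floxed Piezo1 littermates for which no Cre allele was named. Mice of both groups received tamoxifen at 20 mg/kg on 4 consecutive days from 4.5 weeks of age. The comparison asked which transcripts differed in microglia of 5×FAD mice when Piezo1 was deleted in these cells. Only the knockout group was named as carrying the Cre allele. Effects of Piezo1 loss and of that allele therefore cannot be told apart for any listed gene. The values analysed here were normalised read counts of 466 genes that the authors had selected for a difference between the groups. Reads recovered in these genes ranged from 49643 in knockout 2 to 180760 in control 3. These sums cover selected genes and are not library depths, which are unknown here.

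Piezo1 is not among the 466 listed genes, so its level was not analysed here and the genotype labels were not checked by it. The fractalkine receptor gene Cx3cr1, whose locus carries the Cre cassette, was lower in all 3 knockout samples, at 31895 ± 3899 normalised reads against 66461 ± 11266 in controls (mean ± SD, n = 3 each), a 2.08-fold difference. Rps27rt, annotated as a ribosomal protein S27 retrogene, was 3.91-fold lower, at 429 ± 28.4 against 1678 ± 473 normalised reads (SD, n = 3 each). Dusp18, a dual-specificity phosphatase gene, stood at 102 ± 36.0 against 261 ± 78.3 normalised reads (SD, n = 3 each), a 2.55-fold difference. Of the 466 listed genes, 410 were lower and 56 were higher in the knockout.

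In the authors' deposited table, 14 of the listed genes passed an adjusted p of 0.05 over the 19107 genes that the adjustment covered, and all 14 fell in the knockout. Rps27rt fell by 1.97 on the log2 scale (adjusted p = 4.4e-15) and Cx3cr1 by 1.06 (adjusted p = 1.6e-05), both in the authors' deposited table. Dusp18 fell by 1.35 there, with an adjusted p of 0.0363 in the authors' deposited table. The other 11 were Aebp1, Hspg2, Fbn1, Prelp, Col8a1, Tgfbr3, Tnxb, Lamb1, Sulf1, Cttn and 1500015O10Rik. Among the 56 listed genes that were higher, the smallest adjusted p in the authors' deposited table was 0.138, for the zinc finger gene Zfp503. An adjusted p over 0.5 was given there for 402 of the 466 listed genes.

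A fit of the per-sample values with limma called 0 of the 466 genes at an adjusted p of 0.05, and 245 had an unadjusted p under 0.05. edgeR on the recovered reads also called 0, with 246 at an unadjusted p under 0.05, while DESeq2 on the same reads called 48, all lower, of which 12 were among the 14 of the authors' deposited table. The smallest limma adjusted p, 0.0533, was shared by 87 genes, Cx3cr1 and Rps27rt among them. The limma log2 fold change of Cx3cr1 was -1.05 (SE 0.23) and that of Rps27rt was -1.93 (SE 0.42). The exact two-sided permutation p of Cx3cr1 was 0.1, the smallest that 3 against 3 samples can give. The groups did not overlap for 258 genes, 211 of them lower and 47 higher, where chance gives 10% of genes. All of these tests ran on genes chosen on the same samples, so the counts are not independent evidence of a difference. Rescaling the samples to the median ratio of the listed genes turned Cx3cr1 to a log2 fold change of 0.52 (limma adjusted p = 0.577) and brought Rps27rt to -0.36 (limma adjusted p = 0.728). Most of these genes were selected as lower, so the rescaling raised the median log2 fold change of all listed genes by 1.36. Sign changes under it, here and below, follow from that selection and do not test a direction. The number of limma calls went from 0 to 196 without control 1 and to 36 without control 3.

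**Figure D1:**
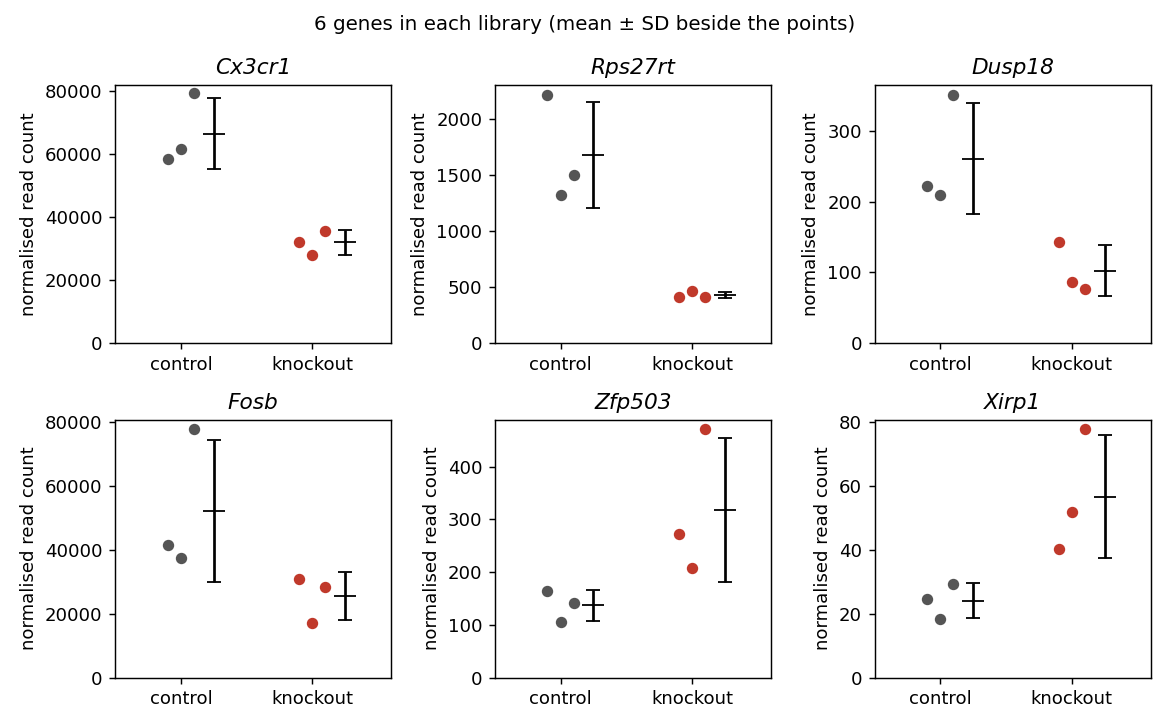
Normalised read count (vertical axis) of 6 genes in the 3 control and 3 knockout samples; points are samples, and the bar beside them is the mean ± SD. Every knockout sample lay below every control sample for Cx3cr1, Rps27rt, Dusp18 and Fosb, and above every control sample for Zfp503 and Xirp1, with none of the 6 under a limma adjusted p of 0.05. Cx3cr1, Dusp18 and Fosb changed sign when samples were rescaled to the median ratio of the listed genes. Most of those genes were selected as lower, so this does not test the direction of the 3 genes.

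Fbn1, Hspg2, Lamb1 and Tnxb, which fell by the authors' adjusted p, encode extracellular matrix proteins, and no list of such genes had been fixed. Fbn1, which encodes fibrillin of the elastic fibre microfibrils, stood at 1.67 ± 0.563 normalised reads in the knockout and 73.3 ± 102 in controls (SD, n = 3 each). Hspg2, the gene of the basement membrane proteoglycan perlecan, stood at 6.01 ± 1.61 against 89.2 ± 101 (SD, n = 3 each). Lamb1, a laminin chain gene, stood at 5.04 ± 3.52 against 48.8 ± 31.7 normalised reads (SD, n = 3 each). Tnxb, which encodes the matrix protein tenascin-X, had no reads in any knockout sample and 24.1 ± 30.1 normalised reads in controls (SD, n = 3 each), at least 7.99-fold lower against a floor of 3 reads per knockout library. This bound was 2.26-fold without control 3. The controls differed widely for these genes: Fbn1 had 3.92, 25.2 and 191 normalised reads in controls 1, 2 and 3, and Hspg2 had 15.7, 47.5 and 205. Sulf1, a heparan sulfatase gene, was instead highest in control 2, with 39.2, 235 and 37.2 normalised reads.

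Most listed genes were present at low levels, and the controls that carried them differed. The median over the 410 lower genes was 18.0 normalised reads in controls and 2.03 in the knockout. Within the controls this median was 6.87, 19.4 and 20.5 normalised reads in samples 1, 2 and 3, and within the knockout it was 1.97, 3.06 and 1.01. Of the 410 lower genes, 224 were highest in control 3, 173 in control 2 and 13 in control 1. A mean of at least 100 normalised reads was reached by 14 of the 466 genes, and 230 had a mean under 10. Protein-coding genes were 396 of the 410 lower genes and 28 of the 56 higher genes (two-sided Fisher's exact test, p = 2.2e-19, with genes as units). Genes are not independent and were selected on these samples, so this p does not measure the spread between samples. Without controls 2 and 3 together, a setting added after the data were examined, 353 of the 410 genes were still lower and 265 were still at least 2-fold lower. The genes had been selected as lower with control 1 among the controls, which favours this outcome even without a difference.

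Genes of microglial states were few among the listed genes, which were 466 of the 19107 genes in the authors' adjustment. At that share, lists of the sizes given below would hold about as few. A low count therefore does not show that the genes of a list were unchanged. Cx3cr1 was the one listed gene of 28 in the homeostatic microglia list, which also holds P2ry12, Tmem119 and Csf1r. None of 36 genes of the disease-associated microglia list was listed, nor any of 37 type I interferon response genes, 27 antigen presentation genes or 23 complement and Fc receptor genes. The cell cycle (47 genes), oxidative phosphorylation (47), ribosomal protein (41), mechanosensitive and ion channel (33) and apoptosis (33) lists likewise had 0 listed genes. A gene that is not listed may have differed by less than the authors' limits and was not analysed here. Ccl22, a chemokine gene and the one listed gene of 43 in the inflammatory list, stood at 4.36 ± 0.647 normalised reads in the knockout and 18.9 ± 5.49 in controls (SD, n = 3 each). Of the phagocytosis list (44 genes), the receptor tyrosine kinase gene Tyro3 and the dynamin gene Dnm1 were listed as lower, with limma log2 fold changes of -1.91 and -1.81. Single lower genes were listed for lysosome and autophagy (Ctsk, of 45), glycolysis and hypoxia (Pfkp, of 32), calcium signalling (Ryr2, of 47) and cytoskeleton and migration (Myl9, of 48). In controls 1, 2 and 3, Myl9 had 0.981, 1.94 and 66.5 normalised reads, Ctsk 31.4, 40.7 and 116, and Pfkp 77.5, 219 and 65.6. Ryr2 was more even there, at 6.87, 11.6 and 8.81. Scd1, a fatty acid desaturase gene of the lipid list, stood at 19.4 ± 15.3 normalised reads against 54.3 ± 31.2 in controls (SD, n = 3 each). Adjusted over the listed members of each list alone, limma called 2 phagocytosis genes and 1 gene each for the homeostatic, inflammatory and calcium lists, against 0 over all 466 genes. For a list with 1 listed gene this is its unadjusted p. The authors had selected every listed member at an unadjusted p under 0.05 on these samples. Calls within a list, here and below, are therefore no evidence for that list. Under the rescaling, Ctsk and Pfkp changed sign.

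Of the 25 genes in the list for the mechanically regulated factors YAP, TAZ and SRF, 5 were listed, all lower: Cyr61, Acta2 and Fhl2, which are targets, and Yap1 and Tead1, which encode YAP and its DNA-binding partner. Yap1 stood at 7.42 ± 6.31 normalised reads in the knockout and 37.0 ± 27.0 in controls, and Cyr61 at 7.96 ± 7.39 against 44.7 ± 60.5 (SD, n = 3 each). The median limma log2 fold change of the 5 was -1.92. limma called 0 of them both over all 466 genes and adjusted over the 5 alone, and 2 had an unadjusted p under 0.05. The median was -2.91 without control 1, -1.41 without control 3, -0.71 without controls 2 and 3 together and -0.52 after the rescaling, and Yap1 changed sign without controls 2 and 3 together. Of the 5 genes, 4 were highest in control 3, where Cyr61 had 114 normalised reads against 7.85 in control 1 and 11.6 in control 2. A two-sided Fisher's exact test of the direction of the 5 against the other listed genes gave an adjusted p of 1 over 3 lists, but with 410 of 466 genes lower it could not pass for a list of this size that is all lower.

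Neuron markers were the largest listed group, with 16 of 51 genes, all lower in the knockout. Snap25, a synaptic vesicle fusion gene, stood at 6.43 ± 7.76 normalised reads against 41.0 ± 27.9 in controls, and Thy1, a surface glycoprotein gene of projection neurons, at 9.79 ± 11.2 against 201 ± 296 (SD, n = 3 each). The NMDA receptor subunit gene Grin1 stood at 1.01 ± 1.02 against 20.1 ± 14.0 normalised reads (SD, n = 3 each). The median limma log2 fold change of the 16 genes was -2.53. It was -1.59 after the rescaling and -1.66 without controls 2 and 3 together. limma called 0 of the 16 over all 466 genes and 11 adjusted over the 16 selected members alone, and 11 had an unadjusted p under 0.05. Of the 16 genes, 12 were highest in control 3 and 4 in control 2, and Syn1 changed sign under the rescaling. Thy1 had 17.7, 42.7 and 542 normalised reads in controls 1, 2 and 3. A two-sided Fisher's exact test of their direction against the other listed genes gave an adjusted p of 0.712 over 3 lists, and could not pass for 16 genes that are all lower.

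Choroid plexus and ependymal markers were listed for 7 of 19 genes, all lower: Ttr, Aqp1, Kcnj13, Otx2, Foxj1, Cldn2 and 1500015O10Rik. All 7 were highest in control 2. Ttr, the transthyretin gene and the most abundant choroid plexus transcript among them, had 3369, 18571 and 265 normalised reads in controls 1, 2 and 3, and 1955, 847 and 563 in knockouts 1, 2 and 3. Aqp1, a water channel gene, had 15.7, 116 and 23.5 normalised reads in controls 1, 2 and 3. The median limma log2 fold change of the 7 genes was -1.98. It was -0.56 after the rescaling and -1.07 without control 2, where Ttr, Otx2 and Foxj1 changed sign, as they did under the rescaling. limma called 0 of the 7 over all 466 genes and 0 adjusted over the 7 alone, with 3 at an unadjusted p under 0.05. The same two-sided Fisher's exact test gave an adjusted p of 1 over 3 lists and could not pass for 7 genes that are all lower.

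**Figure D2:**
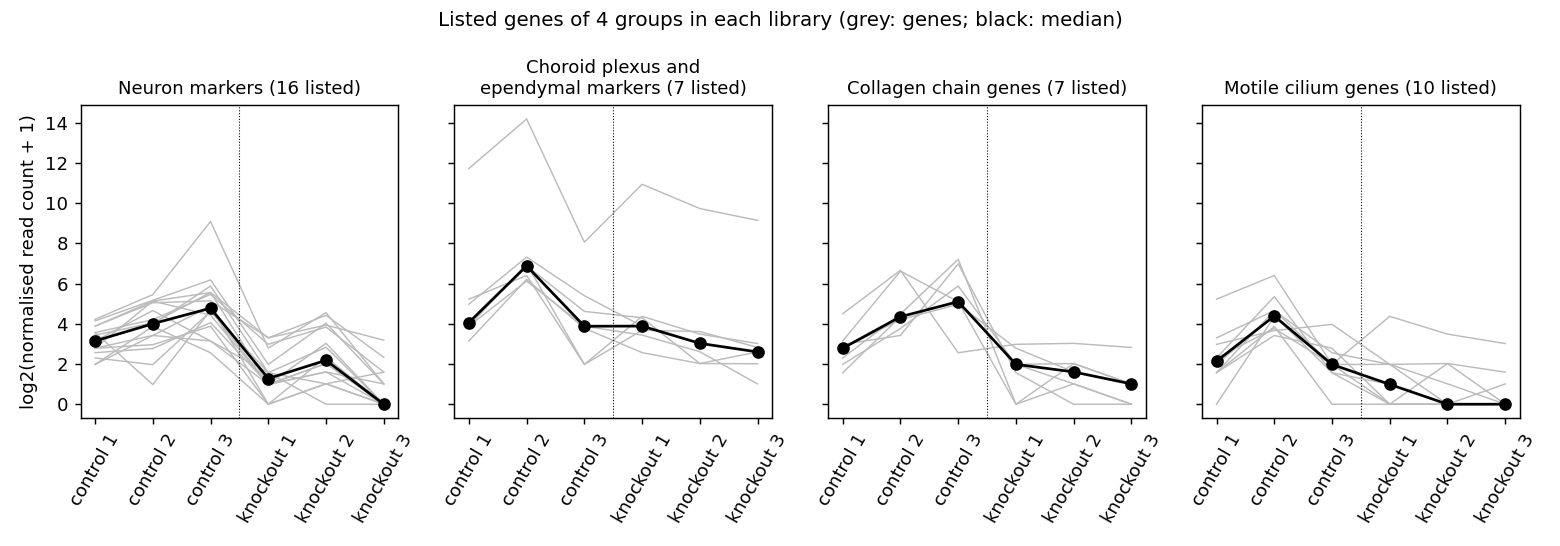
Listed members of 4 gene groups in each of the 6 samples, as log2(normalised read count + 1) on the vertical axis; grey lines are genes and black points are medians. Medians of the 16 neuron markers and 7 collagen genes were highest in control 3, and those of the 7 choroid plexus and ependymal markers and 10 motile cilium genes were highest in control 2.

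Markers of other cell types were also listed, nearly all as lower. Of the erythroid and mast cell list, the globin gene Hba-a1 had a limma log2 fold change of -4.53 and the globin gene Hbb-bs one of -3.72. Hbb-bs stood at 7.82 ± 11.02 normalised reads against 73.7 ± 51.3 in controls (SD, n = 3 each). Knockouts 1, 2 and 3 had 0, 20.4 and 3.04 normalised reads of Hbb-bs and 0, 8.17 and 0 of Hba-a1. The log2 fold change of Hbb-bs was -2.65 without knockout 1 and -4.86 without knockout 2. Hba-a1 and Hbb-bs have near-identical copies in the genome, so their reads are uncertain. Mural and fibroblast genes (4 of 24) were Acta2, Igfbp2, Apod and Ptgds, with a median limma log2 fold change of -1.82. Igfbp2, an insulin-like growth factor binding protein gene, had 77.5, 364 and 29.4 normalised reads in controls 1, 2 and 3. Astrocyte genes (3 of 30) were Gja1, Sox9 and Htra1, endothelial genes (2 of 28) were Pltp and Spock2, and the oligodendrocyte list (28 genes) gave Gsn, and Pltp, Spock2 and Gsn changed sign under the rescaling. Adjusted over the listed members of each list alone, limma called 1 border macrophage gene and 0 of the mural, astrocyte, endothelial, oligodendrocyte, monocyte and T and NK cell genes. Cd209a, in both the border macrophage (20 genes) and the monocyte and dendritic (25 genes) lists, was lower, at 4.02 ± 1.00 against 13.3 ± 1.42 normalised reads (SD, n = 3 each). Clec4n, another border macrophage marker and the one higher gene among the listed cell type markers, stood at 5.00 ± 2.59 against 0.326 ± 0.565 normalised reads (SD, n = 3 each). Bcl11b was the one listed gene of 29 T and NK cell markers, and 0 were listed of 16 oligodendrocyte precursor, 22 neutrophil and 18 B and plasma cell markers. Of 32 immediate early genes that tissue dissociation is known to induce, Fosb was listed, at 25499 ± 7479.9 against 52206 ± 22189 normalised reads (SD, n = 3 each). limma called Fosb by its unadjusted p, as the 1 listed gene of its list, and not over all 466 genes.

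Genes listed as higher in the knockout included Zfp503, at 317 ± 137 normalised reads against 137 ± 29.3 in controls (SD, n = 3 each), a 2.32-fold difference. Pde10a, a cyclic nucleotide phosphodiesterase gene, stood at 49.6 ± 18.7 against 19.2 ± 5.41, and Ankle1, an endonuclease gene, at 49.4 ± 10.5 against 20.9 ± 14.3 normalised reads (SD, n = 3 each). Kntc1, a kinetochore gene, stood at 79.8 ± 14.9 against 36.5 ± 19.7, and Neil3, a DNA glycosylase gene, at 46.2 ± 1.48 against 22.5 ± 12.3 normalised reads (SD, n = 3 each). The smallest limma adjusted p among these 5 genes was that of Zfp503, at 0.105. Hist2h4 was also higher, but belongs to a family of near-identical histone genes whose reads are uncertain.

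Both of the genes with the smallest adjusted p in the authors' deposited table lie on chromosome 9 (GRCm38). Cx3cr1 (ENSMUSG00000052336) spans positions 119901616 to 120069879 and Rps27rt (ENSMUSG00000050621) spans 114982366 to 114982739, and their starts are 4.92 Mb apart. Within 10 Mb of the Cx3cr1 start, 5 genes were listed, which are Cx3cr1, Rps27rt, Xirp1, Myrip and Trank1. Xirp1, a gene of an actin-binding muscle protein, stood at 56.8 ± 19.2 normalised reads in the knockout and 24.1 ± 5.48 in controls (SD, n = 3 each). It lies inside the annotated span of Cx3cr1 on the same strand, so its reads are uncertain. Myrip and Trank1, named here after their values were seen, were listed as lower, with adjusted p-values of 1.00 in the authors' deposited table. The Rps27rt transcript matched an Rps27 transcript over 91.2% of its length at 100% identity, so its reads are uncertain as well.

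**Figure D3:**
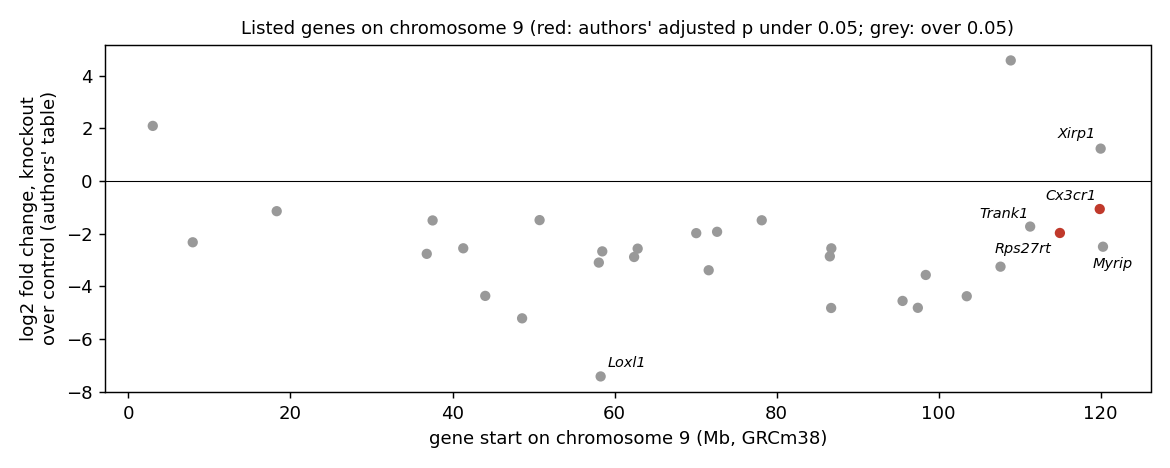
Start of each of the 32 listed genes on chromosome 9 (horizontal axis, Mb) against the log2 fold change of knockout over control in the authors' deposited table (vertical axis); red points had an adjusted p under 0.05 there. The 2 red points are Rps27rt and Cx3cr1.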

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

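Chosen after the results were seen were the runs without controls 2 and 3, edgeR, adjustment over 19107 genes, the thresholds on the authors' adjusted p, and every setting run on list medians and on the split into lower and higher genes. The number of genes called by limma at an adjusted p of 0.05 was 0 of 466 (245 at an unadjusted p under 0.05). From there, a threshold of 0.01, added fold limits and adjustment over 19107 genes or all annotated genes could only give 0. The number was also 0 with a pseudocount of 10, no trend and edgeR on the recovered reads. It was 120 with a pseudocount of 0.5, 1 with a mean of at least 10, 2 with a mean of at least 100, 48 with DESeq2 on the recovered reads, 56 after rescaling to the median ratio of the listed genes (10 lower, 46 higher) and 54 without controls 2 and 3, of which 53 had no reads in any knockout sample. Leaving out 1 sample in turn gave 0 to 196 genes, 196 without control 1 and 36 without control 3. A fit with the replicate number as a block called 4 genes, Cx3cr1, Loxl1, Fosb and Hba-a1. Same-numbered samples correlated at -0.04, -0.04 and 0.07 across the selected genes, after the group means were taken off. With 3 samples per group and many of these genes high in single controls, this cannot tell whether the numbers pair the samples. No sample correlated best with its own number. The authors' adjusted p passed 0.01 for 6 genes and 0.1 for 22.

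Cx3cr1 expression had a limma log2 fold change of -1.05 with the replicate block (adjusted p = 0.00947), with a pseudocount of 0.5 (0.0441) and with a mean of at least 100 (0.0187), each past the threshold, and of -1.14 to -0.92 when each sample was left out (adjusted p 0.0324 to 0.164). After the rescaling it was 0.52, and Rps27rt went from -1.93 to -0.36. The rescaling moved the median of all listed genes by 1.36 on the log2 scale and split them into 372 lower and 94 higher. It rests on genes selected as lower, which shows the cause of the reversals under it: Dusp18 0.21, Fosb 0.57, Gsn 0.59, Pltp 0.47, Pfkp 0.60, Spock2 0.16, Otx2 0.49, Ctsk 0.43, Syn1 0.26, Foxj1 0.50 and Ttr 0.19. Without control 2, Otx2, Foxj1 and Ttr reversed; leaving out 1 sample in turn gave -2.06 to 0.44 for Otx2, -2.19 to 0.025 for Foxj1 and -3.02 to 0.046 for Ttr. Without controls 2 and 3, Htra1 (0.62) and Yap1 (0.054) reversed. The cause of these 5 was not tested. List medians that moved by more than 1 SD of the list's median between samples of a group were those of neuron markers (-0.91), collagen (-1.27), homeobox (-0.58) and motile cilium genes (-0.70) with a pseudocount of 10, of mural and fibroblast markers without controls 2 and 3 (-0.88) and after rescaling (-0.31), and of collagen genes without controls 2 and 3 (-1.47). Within that SD, more medians moved by over 1.5 times, among them these: without controls 2 and 3, those of astrocyte markers went from -1.84 to -0.14 and of the YAP, TAZ and SRF list from -1.92 to -0.71, and after rescaling those of that list went to -0.52, of choroid plexus and ependymal markers from -1.98 to -0.56 and of astrocyte markers to -0.83. The direction test of neuron markers gave an adjusted p of 0.0481 (Fisher's exact test) without controls 2 and 3, but there the control arm is 1 sample and the units are genes, so it shows no difference between the groups. The 410 lower genes stayed lower for 398 to 410 when 1 sample was left out. With 230 genes under a mean of 10, counting error limits most single values. Of 1285 values of other named genes under the alternatives, 1163 kept their direction and side of the threshold, 106 passed it and 16 reversed. Not run were the alternatives for Piezo1, which is not listed, and the direction tests on genes past the adjusted p alone, with or without the block, since limma called too few genes.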

Other observations

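The tests of explanations in this part, which are both contrasts between gene groups, the share for control 1, the ratio intervals and the transcript match, as well as the count of other splits and the edgeR run, were chosen after the results were seen, while the limma and DESeq2 counts were planned. Of the 10 listed motile cilium genes, which include Foxj1 of the ependymal list, all were lower in the knockout and 9 were highest in control 2. Their median limma log2 fold change was -2.21, or -1.80 with the 3 genes that had no reads in any knockout sample set at their bound, and -1.35 without control 2. Of the 7 listed collagen chain genes, from a group of 44, all were lower and 5 were highest in control 3, as were 224 of all 410 lower genes. Their profiles differed: Col8a1 had 7.85, 97.0 and 33.3 and Col8a2 21.6, 99.9 and 4.89 normalised reads in controls 1, 2 and 3. Col6a1, a chain of a microfibrillar collagen, had 3.92, 21.3 and 147 normalised reads in controls 1, 2 and 3, and 0.340 ± 0.590 in the knockout (SD, n = 3). The 7 listed genes given the transcription factor family Homeobox in the deposited table were all lower, and 6 were highest in control 3. Their median was -2.15, or -1.11 with the 5 genes that had no reads in any knockout sample at their bound, and -0.98 without control 3. That label does not cover every listed homeobox gene: Otx2, highest in control 2, is not among the 7. These groups were chosen after the table was seen.

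The first pattern is the lower level in the knockout of markers of cells other than microglia, the most abundant of which were Ttr (18571 normalised reads in control 2), Gsn (834 in control 3) and Thy1 (542 in control 3). A candidate explanation is RNA of other cells, present in different amounts in single control samples, and it was tested with 2 contrasts of the log2 ratio of control 2 over control 3 between gene groups. The first contrast set the 7 choroid plexus and ependymal markers against the 7 collagen genes, with a difference of medians of 3.19, and its exact permutation p of 0.0583 missed the limit of 0.05 set for it. The second contrast replaced it after that miss and set the same 7 markers against the 16 neuron markers, with a difference of 3.56 and an exact permutation p of 0.000489. Adjusted over both contrasts by the Benjamini-Hochberg method, the p-values are 0.0583 and 0.000979, but this does not account for the choice of the second contrast after the sample profiles of both groups had been seen.

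The second contrast therefore restates that the choroid plexus markers were highest in control 2 and most neuron markers in control 3, and neither contrast supports an explanation on its own. Their p-values compare 2 single samples, permute genes, which are not independent, and use members that the authors selected on these samples. Neither contrast (3.19 and 3.56) used a knockout sample, so the exact permutation p of the second, 0.000489, does not test a genotype effect. Other cells in single control samples and a genotype effect in microglia as the whole cause cannot be told apart on this ground. The same holds for a source of collagen transcripts apart from that of the choroid plexus markers. The controls share a genotype label, which cannot give the spread among them. Medians in controls 1, 2 and 3 were 15.7, 116 and 13.7 normalised reads for the choroid plexus markers. They were 7.85, 15.0 and 26.4 for the neuron markers, and the source of this spread was not tested. In control 3, Ttr, Otx2 and Foxj1 lay below every knockout sample and the other 4 choroid plexus markers above, which goes against a genotype effect as the whole cause for those 3 genes but rests on 1 sample. How many of these markers microglia also express was not tested, and no sort or gate that would remove other cells is given in the sources used here. A genotype effect beside other cells also stays open: control 1, which had the lowest median of the 410 lower genes among controls (though not of the choroid plexus markers), lay at or below the knockout mean for a share of 0.139 of the 410 lower genes (57 genes) and above every knockout sample for 275, which other cells in control 1 could also give. The 410 genes had also been selected as lower with control 1 among the controls, which by itself favours these counts.

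The second pattern is Cx3cr1 at 0.480 of its control level, from the log2 fold change in the authors' deposited table. The Cre cassette is known to replace the coding sequence of the Cx3cr1 copy that carries it, and the loss of 1 of 2 copies would give 0.5. That value lies in both 95% intervals of the ratio, 0.338 to 0.686 from limma and 0.378 to 0.609 implied by the authors' fold change and p, which is consistent with copy loss if the mice carried 1 cassette copy. The intervals were set against 0.5 when the ratio was already known. An effect of Piezo1 loss on Cx3cr1 stays open and untested, since every knockout sample carried the cassette.

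The third pattern is Rps27rt at 0.255 of its control level, 4.92 Mb from Cx3cr1. After rescaling to the listed genes its log2 fold change was -0.36, and the ratio of 0.255 holds for the authors' scaling. The highest knockout sample was at 0.350 of the lowest control sample, which goes against loss of 1 of 2 linked copies as the whole cause, but the test of a ratio of 0.5 depends on which of 2 intervals is used. The 95% interval from limma, 0.136 to 0.503, was computed first and holds 0.5 near its upper end. Its width does not rest on Rps27rt alone, since limma borrows variance from the other listed genes, most of them low. The interval implied by the authors' fold change and p, 0.190 to 0.344, was computed afterwards, was at first put in its place and excludes 0.5, so with both kept the explanation cannot be told apart from others. Reads shared with Rps27, whose transcript matches 91.2% of that of Rps27rt, may also contribute, which stays open because Rps27 was not analysed here, as does a linked strain difference, which was not tested.

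At an adjusted p of 0.05, limma called 0 genes for the real split of the 6 samples (245 at an unadjusted p under 0.05; edgeR 0, DESeq2 48), and at most 1 for any other split; against a real count of 0 the 10 splits decide nothing. At an unadjusted p under 0.05 the real split gave 245 genes and the highest other split 36, so 1 of 10 splits gave as many. With 10 splits the share is never under 0.1, too few for a share under 0.05, and the genes had been selected on the real split.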
